A study of Mus musculus with 20 samples.

How the data were processed

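Liver RNA from 20 male Balb-C mice was measured with TempO-Seq, an assay in which pairs of short detector oligonucleotides anneal next to each other on a target RNA, are ligated, amplified and counted by sequencing. Per the labels' protocols, the mice were 10 to 12 weeks old, were dosed by gavage once a day for 7 days with Nafion byproduct 2, and each library comes from a separate animal. The groups were a vehicle control and doses of 0.03, 0.3, 3 and 6 mg/kg per day, with 4 mice each. The protocols name deionized water as the vehicle, whereas the sample titles of the controls carry the word DMSO; which was given is not settled here.

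The deposited table holds raw counts per probe, 1 column per mouse, with no normalization by the authors that the values show. Per the submitters' processing notes, Bowtie and the mouse build GRCm38.p5 were used; the version of Bowtie and the settings for counting probes are not given in the sources used here. The table has 30146 probes for 21450 gene symbols, and 6290 symbols have more than 1 probe. No row lacks a gene name and no column is without a sample. Replicates carry no number in the labels and were numbered in accession order, which pairs nothing.

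Library totals ran from 6823518 to 10310931 counts, so that 3 counts correspond to between 0.251 and 0.511 CPM (counts for every 1000000 counts of the library) across libraries. No copy was found among libraries of the same group, where the lowest ratio of chi-square to its degrees of freedom over 30 pairs was 4.03; pairs from different groups were not tested. Intervals and floors of this kind cover counting error only, since amplified reads are not independent molecules.

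Probes were kept by the default rule of filterByExpr in edgeR 4.0.16 under R 4.3.3, which left 14122 probes of 10101 genes holding 99.8% of the counts. Factors from the trimmed mean of M values (TMM) scaled the libraries. A quasi-likelihood model with robust spread was fitted to all 20 libraries with 1 mean per group, and p-values were adjusted by Benjamini-Hochberg over the probes of each comparison, with 0.05 as the threshold. Each dose was compared with control, 6 mg/kg was compared with 3 mg/kg, and a slope over dose rank was tested. CPM values use the TMM-scaled library sizes. Fold changes are on the log2 scale with their standard errors (SE), and adjusted p-values in the text come from this edgeR test unless another tool is named.

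For statements about genes, the probe with the highest mean count stood for its gene. Gene lists for 36 pathways, stress responses and cell types were fixed before the data were examined. They were tested at each dose with camera in limma 3.58.1 at a preset correlation of 0.01, with p-values adjusted over the 144 tests, and again with a correlation estimated per list and with fry. Named genes follow a rule that was also fixed before the data were examined. It takes up to 8 risers and 8 fallers per dose, with a mean of at least 20 CPM and no overlap between the treated and control libraries. It adds up to 2 members per list and direction with the smallest p, a fixed set of sentinel genes whatever their values, and 5 genes per direction for the slope and for 6 against 3 mg/kg. Some genes that the rule names are not reported here. Coordinates are from the GENCODE M21 annotation of GRCm38 and give the gene, since probe positions were not used here.

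Alternatives fixed before the data were examined were other scalings, other count filters, DESeq2 1.42.0, limma-voom, a fit that is not robust, probes summed per symbol, fits on the 8 libraries of a comparison, minimum folds, other dose scales, plate row as a covariate, and each library left out in turn. Plate rows and columns were read from the sample titles. Chosen after seeing the data were fits without 2 libraries that stand apart, plate column as a covariate, and removal of each library's trend on transcript GC content.

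The functions were tested on simulated counts with 200 changed probes, drawn from the control means, library sizes and fitted dispersions. For 6 mg/kg against control, over 13621 simulated probes, edgeR recovered 1.49% of the changes of 1.5-fold, 37.9% of those of 2-fold and 89.1% of those of 4-fold, and 3 of its 86 calls were false. Under no change, edgeR called 0 probes for 3 mg/kg against control. DESeq2 recovered 49.3% of the 2-fold changes with 11 false calls of 107.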

Results

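Nafion byproduct 2 is a fluorinated ether sulfonic acid formed in the manufacture of a fluoropolymer membrane. The transcript level of livers from male Balb-C mice was measured after 7 days of oral dosing once a day, with 4 mice in each of 5 groups: a vehicle control and the doses 6, 3, 0.3 and 0.03 mg/kg per day. Library totals ran from 7123004 to 9890662 counts in the control group, from 9425085 to 9945290 at 0.03 mg/kg and from 8836482 to 10310931 at 0.3 mg/kg. They ran from 6823518 to 9177664 counts at 3 mg/kg and from 8173468 to 8477663 at 6 mg/kg. Probes for major urinary proteins took 16.3% ± 3.70 (SD, n = 4) of the counts in control livers, 17.2% ± 1.46 at 0.03, 12.5% ± 5.04 at 0.3, 17.1% ± 7.61 at 3 and 8.90% ± 4.09 at 6 mg/kg, where dose_6 replicate 4 held 2.96% and the other 3 held 10.0% to 12.3%. The mean correlation of a library with the rest of its group was at least 0.942 in 18 libraries, 0.870 in dose_3 replicate 4 and 0.940 in dose_6 replicate 4. Control and 0.03 mg/kg libraries came from plate row A and the 3 and 6 mg/kg libraries from row B, and only the 0.3 mg/kg group had wells in both.

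The first comparison asks what the lowest dose changed. No sentinel gene passed at 0.03 mg/kg. Cyp2b10, a cytochrome P450 that responds to the receptor CAR, was at 72.4 ± 28.3 CPM (SD, n = 4) against 62.3 ± 26.6 CPM (SD, n = 4) in controls. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was at 288 ± 45.2 CPM against 282 ± 50.6 CPM. Hsd3b5, a steroid dehydrogenase of the male liver, was at 41.5 ± 1.71 CPM against 37.8 ± 5.83 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay at 14.3 to 31.5 CPM against 4.53 to 10.6 CPM in controls, a log2 of 1.68 (SE 0.82). Fgf21, a fasting hormone, was at a log2 of -1.64 (SE 0.55), but control replicate 1 held 5.49 CPM against 0.755 to 1.82 CPM in the other 3 controls, and the 0.03 mg/kg libraries held 3 to 12 counts. The omega-hydroxylases of fatty acids Cyp4a14 and Cyp4a10 were at -1.31 (SE 0.64) and -1.31 (SE 0.71). No probe passed the edgeR test, 457 had an unadjusted p under 0.05 where 706 are expected by chance, limma-voom called 0 and DESeq2 called 1. Of the 36 gene lists, 10 were called by camera at the preset correlation. Among them were erythroid markers (median 0.85 in 5 members, adjusted p = 0.00027), lymphocyte and neutrophil markers (median -0.62 in 11, adjusted p = 0.00071) and Kupffer cell markers (median -0.15 in 18, adjusted p = 0.0062), at 0.13, 0.35 and 0.40 with an estimated correlation. With an estimated correlation 1 was, amino acid catabolism and urea cycle, with a median log2 change of 0.12 and an adjusted p of 0.016, which was 0.088 without dose_3 replicate 4 and dose_6 replicate 4.

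At 0.3 mg/kg, Cyp2b10 stood at 167 ± 43.0 CPM (SD, n = 4), a log2 fold change of 1.43 (SE 0.39) that missed the threshold over all probes (edgeR adjusted p = 0.417). Of the 54 measured target genes of CAR and PXR, receptors that induce drug-metabolizing enzymes, 0 passed over all probes, while 6 were higher and 2 lower when adjusted over the list alone. The list of cholesterol synthesis genes had a median log2 change of 0.38 in 27 members, with 0 members called and an adjusted camera p of 2.7e-06, and an adjusted p of 0.18 with an estimated correlation. The adjusted camera p of the CAR and PXR list was 0.00045, and 0.40 with an estimated correlation. The interferon response list had a median of -0.31 in 34 members, with an adjusted camera p of 0.00018 and an adjusted p of 0.40 with an estimated correlation. Beside it, lymphocyte and neutrophil markers had a median of -0.73 in 11 members, with an adjusted camera p of 0.00047 and an adjusted p of 0.34 with an estimated correlation. No probe passed the edgeR test, 1175 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 42, of which 37 were lower. The fit on the 8 libraries compared called 4, and leaving out dose_0.3 replicate 2 gave 1. Of the 4 libraries at 0.3 mg/kg only replicate 4 came from plate row B, and the fit without it called 0.

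At 3 mg/kg, genes of drug metabolism and of cell division rose. Cyp2b10 went from 62.3 ± 26.6 CPM to 581 ± 171 CPM (SD, n = 4), a log2 fold change of 3.22 (SE 0.42, edgeR adjusted p = 0.00031). Cyp2c66, another cytochrome P450, rose from 0.490 to 90.5 CPM, and since its control level was near the floor of 3 counts its log2 fold change of 7.54 (SE 0.53) is imprecise at the low end. Gadd45b, a stress-inducible gene, rose by a log2 of 3.23 (SE 0.36), and Por, the reductase that serves the P450 enzymes, by 1.98 (SE 0.34). In all, 211 probes of 175 genes passed, 157 higher and 54 lower, against 203 higher and 176 lower without dose_3 replicate 4 and dose_6 replicate 4, which stood apart from their groups.

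Of the 54 CAR and PXR targets, 21 rose and 0 fell at 3 mg/kg (median log2 change 0.76), and 29 were higher and 1 lower adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.018). Of 37 cell cycle genes, 16 rose and 0 fell (median 1.79; 25 adjusted over the list alone), among them Mcm6, a subunit of the replicative helicase, at 2.67 (SE 0.26), and Kif20a, a mitotic kinesin, at 2.52 (SE 0.30), with an adjusted p of 0.0049 with an estimated correlation. Of 38 target genes of NRF2, a regulator of the oxidative stress response, 8 rose and 0 fell (median 0.40; 11 adjusted over the list alone), with an adjusted p of 0.019 with an estimated correlation. They include Gstm3, a glutathione transferase, at 1.02 (SE 0.16), and Ugdh, which makes UDP-glucuronic acid, at 0.98 (SE 0.18). The NRF2 list shares Gstm3, Gsta1, Abcc4 and other genes with the CAR and PXR list, so the results of these lists are not independent. Of 59 target genes of PPARalpha, the receptor of fatty acid oxidation, 2 rose, Ehhadh at 0.77 (SE 0.19) and Fabp4 at 0.80 (SE 0.17). Adjusted over the list alone 7 were higher and 1 lower, and the adjusted p with an estimated correlation was 0.40. Cyp4a14 was at a log2 of 1.66 (SE 0.50), which did not pass (edgeR adjusted p = 0.13). The main probe of Cyp4a10 did not pass at 1.93 (SE 0.69), while its other probe passed at 5.65 times the control level (edgeR adjusted p = 0.028). Without dose_3 replicate 4 and dose_6 replicate 4, 29 CAR and PXR targets, 19 cell cycle genes and 11 NRF2 targets rose and 0 fell, but the adjusted p with an estimated correlation was then 0.051 for each of the 3 lists.

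Other genes that rose at 3 mg/kg were Ces2a, a carboxylesterase, at a log2 of 1.72 (SE 0.26), Tsku at 2.60 (SE 0.52), Gm3776 at 2.69 (SE 0.33) and Fdft1, a squalene synthase, at 0.74 (SE 0.14). Cyp7a1 passed at 3.65 (SE 0.86), but 1 library held 348 CPM and the other 3 held 13.8 to 20.8 CPM. Without dose_3 replicate 4 it was at 1.08 and did not pass (edgeR adjusted p = 0.308), nor did it pass when any 1 of the 4 controls was left out. The main probe of Cyp3a11, a P450 induced through PXR, did not pass at -0.35 (SE 0.54), while its other probe rose by 1.59 (SE 0.33). Near-identical genes of the Cyp2c, Cyp3a, Gsta and Ces families can share probe signal, which was not tested. A change may therefore belong to another member of the family than the one named.

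Genes that fell at 3 mg/kg included Oaf at a log2 of -2.76 (SE 0.68), Dpy30 at -2.14 (SE 0.50), Gjb1, a gap junction protein of hepatocytes, at -2.11 (SE 0.52), Psenen at -2.06 (SE 0.46), Scly at -1.62 (SE 0.31) and Srsf9 at -1.33 (SE 0.22). Where a gene had another tested probe, that probe did not follow these falls. It stood at 0.08 for Dpy30, -0.13 for Psenen, -0.11 for Scly and 0.02 for Srsf9, and none of the 4 passed. Over all falling probes at 3 mg/kg that had another probe of their gene, 0 of 25 were matched by a call in the same direction, against 64 of 100 among rising probes. The median log2 change of those other probes was -0.09 for falling and 1.72 for rising probes. A gene with more than 1 called probe enters once for each, which raises the share matched among rising probes. The 157 rising probes come from 122 genes and the 54 falling probes from 54.

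**Figure D1:**
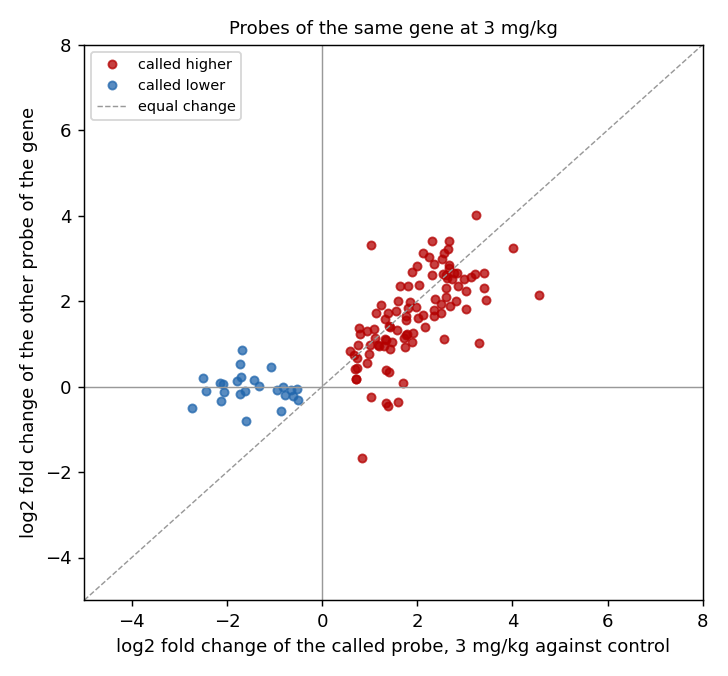
Log2 fold change at 3 mg/kg against control of each called probe (horizontal axis) and of the most counted other probe of the same gene (vertical axis), 1 point per called probe, with red for called higher, blue for called lower and a dashed line for equal change. Of the 100 red points 95 lie above 0 on the vertical axis, with a median of 1.72. The 25 blue points have a median of -0.09 there, and those farthest from 0 are Abhd5 at 0.85 and Alox5ap at -0.80.

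The number of calls at 3 mg/kg was lower without any 1 of the controls: 124, 132, 142 and 128 probes were called without control replicate 1, 2, 3 and 4. The counts are alike, so they do not mark out a particular control, and a smaller control group also detects less. The fit on the 8 libraries compared called 44, 41 higher and 3 lower, and DESeq2 called 356, 231 higher and 125 lower. With plate row as a covariate, estimated from the 0.3 mg/kg group alone, 1 probe was called, since the median SE of the 211 probes went from 0.33 to 0.66 while their median absolute log2 change went from 1.73 to 1.49 and 208 had the same sign.

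At 6 mg/kg, Cyp2b10 reached 2149 ± 1238 CPM (SD, n = 4), a log2 fold change of 5.11 (SE 0.46, edgeR adjusted p = 3.9e-07). Cyp4a14 reached 114 ± 34.0 CPM from 1.58 ± 1.46 CPM, a log2 of 6.19 (SE 0.50), and Cyp4a10 rose by 4.21 (SE 0.75). Gsta1, a glutathione transferase, went from 23.6 ± 3.71 to 1606 ± 173 CPM, a log2 of 6.09 (SE 0.70), Cyp2c66 rose by 8.25 (SE 0.53), Gadd45b by 5.65 (SE 0.38), Cyp2c55 by 5.40 (SE 0.68) and Gm3776 by 4.90 (SE 0.36). In all, 2867 probes of 2454 genes passed, 1634 higher and 1233 lower, against 2003 higher and 1958 lower without dose_3 replicate 4 and dose_6 replicate 4. Cyp2b10 lies on chromosome 7 from 25897620, Cyp4a14 on chromosome 4 from 115486200, Cyp2c66 on chromosome 19 from 39113898 and Gsta1 on chromosome 9 from 78230656.

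Of the 54 CAR and PXR targets, 42 rose and 1 fell at 6 mg/kg (median log2 change 1.99; adjusted p = 0.0053 with an estimated correlation), and 43 were higher and 1 lower adjusted over the list alone. Of 37 cell cycle genes, 31 rose and 0 fell (median 3.08, adjusted p = 0.0049 with an estimated correlation), with Kif20a at 4.14 (SE 0.31). Of 38 NRF2 targets, 31 rose and 0 fell (median 1.11, adjusted p = 0.0049 with an estimated correlation), with Gstm3 at 2.45 (SE 0.17), Ugdh at 2.14 (SE 0.18) and Nqo1, a quinone reductase, at 2.16 (SE 0.20). Gstm3 and other NRF2 targets are also counted in the CAR and PXR list. Adjusted over the list alone, 31 cell cycle genes were higher and 0 lower, and 31 NRF2 targets were higher and 1 lower. Without dose_3 replicate 4 and dose_6 replicate 4, 45 CAR and PXR targets rose and 1 fell, and 32 cell cycle genes and 30 NRF2 targets rose, but the adjusted p with an estimated correlation was then 0.051 for each of the 3 lists.

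PPARalpha targets rose in 33 of 59 members and fell in 4 at 6 mg/kg (median 0.71; adjusted p = 0.019 with an estimated correlation, and 0.11 without the 2 libraries that stood apart), and 39 were higher and 4 lower adjusted over the list alone. Ehhadh rose to 1416 ± 235 CPM from 282 ± 50.6 CPM, a log2 of 2.33 (SE 0.19), and Pdk4, which restrains glucose oxidation, rose by 2.29 (SE 0.52). Cpt1a, the carnitine transferase of mitochondrial uptake, was at 0.72 (SE 0.34) and Fabp1, a fatty acid binding protein, at 0.37 (SE 0.19), and neither passed. Fgf21 fell from 2.37 ± 2.13 CPM in controls to 0.170 ± 0.151 CPM, which is under the floor of 3 counts, and the main probe of the receptor itself, Ppara, fell by 0.81 (SE 0.17), while its 2 other probes did not pass at -0.41 (SE 0.21) and -0.62 (SE 0.32). Mitochondrial oxidation genes rose in 14 of 34 members and fell in 1, with Acot2 at 3.51 (SE 0.31), and the adjusted p with an estimated correlation was 0.085. Omega-hydroxylation genes rose in 7 of 13 and fell in 1, with an adjusted p of 0.081 with an estimated correlation. Peroxisomal genes rose in 12 of 43 and fell in 6, which camera did not call (adjusted p = 0.18).

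Of 27 cholesterol synthesis genes, 19 rose and 0 fell at 6 mg/kg (median 1.06), and the adjusted p with an estimated correlation was 0.077. Of 30 fatty acid synthesis genes, 17 rose and 0 fell (median 0.77, adjusted p = 0.019 with an estimated correlation, and 0.13 without the 2 libraries that stood apart), with Fasn, the fatty acid synthase, at 3.10 (SE 0.42), Scd1, a desaturase, at 2.59 (SE 0.37) and Elovl6, an elongase, at 1.95 (SE 0.19). Bile acid genes went both ways in 8 and 6 of 34 members. Among them Cyp7a1 passed at 3.01 (SE 0.84), a call lost without control replicate 3 (2.81, edgeR adjusted p = 0.0522), and Cyp8b1, which makes cholic acid, rose by 1.14 (SE 0.25).

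**Figure D2:**
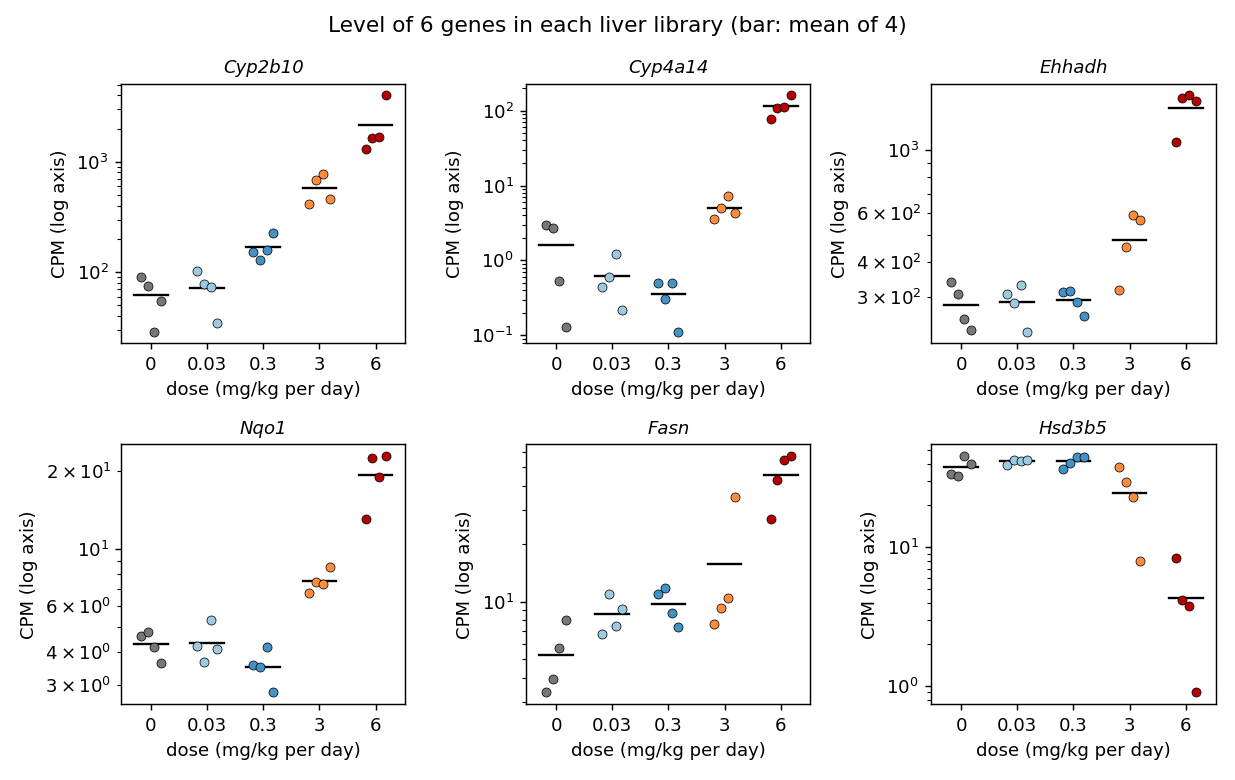
Level in CPM, on a log axis, of 6 genes in each of the 20 libraries by daily dose in mg/kg, with 1 point per mouse and a bar at the mean of 4. All 4 libraries at 6 mg/kg lie above all controls for Cyp2b10, Cyp4a14, Ehhadh, Nqo1 and Fasn, and below them for Hsd3b5.

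Of 49 complement and coagulation genes, 18 fell and 1 rose at 6 mg/kg (median -0.45, adjusted p = 0.028 with an estimated correlation, and 0.051 without the 2 libraries that stood apart), with C9, a terminal complement component, at -1.96 (SE 0.22) and C1ra at -3.63 (SE 0.45). Albumin, Alb, fell by 0.82 on the log2 scale (SE 0.24). Hsd3b5 went from 37.8 ± 5.83 to 4.31 ± 3.09 CPM, a log2 of -3.15 (SE 0.45), and Socs2, a growth hormone target, was at -2.55 (SE 0.49), with its other probe at -2.25. Of 37 male-biased genes, 13 fell and 4 rose, and of 25 female-biased genes 11 rose and 3 fell. The female-biased list shares Cyp2b9, Cyp2a4, Cyp3a44 and other genes with the CAR and PXR list. The adjusted p with an estimated correlation was 0.52 for the male-biased and 0.45 for the female-biased list. Other large falls were Gm10681 at -2.72 (SE 0.33), Serpina4-ps1 at -2.83 (SE 0.60), Car14, a carbonic anhydrase, at -2.50 (SE 0.48), Gjb1 at -3.01 (SE 0.55), Fam96a at -2.89 (SE 0.53) and Rps27l at -2.85 (SE 0.61). The other probe of Rps27l stood at 0.06 and did not pass. Among falling probes at 6 mg/kg with another probe of the gene, 208 of 621 were matched by a call in the same direction, against 481 of 896 among rising probes. The other probe had the same sign for 81.3% of the falling and 86.6% of the rising probes. The falls were also smaller, with a median of -0.84 against 1.15. These counts are per probe, and the 1634 rising probes come from 1350 genes and the 1233 falling probes from 1114.

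Interferon response genes fell in 16 of 34 members and rose in 0 at 6 mg/kg (median -0.68), with Irf1, a transcription factor of the response, at -0.91 (SE 0.14) and Igtp, an interferon-induced GTPase, at -1.26 (SE 0.23). The adjusted p was 0.34 with an estimated correlation. Markers of other liver cells moved beside them: 4 of 18 Kupffer cell markers fell, including C1qb at -1.18 (SE 0.22; adjusted p of the list 0.38 with an estimated correlation), 4 of 11 lymphocyte and neutrophil markers fell and 1 rose, and 10 of 23 stellate cell markers fell and 4 rose. Endothelial markers rose in 2 and fell in 2 of 23, with a median of -0.01. S100a8, listed as a neutrophil marker, rose by 4.92 (SE 0.45).

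**Figure D3:**
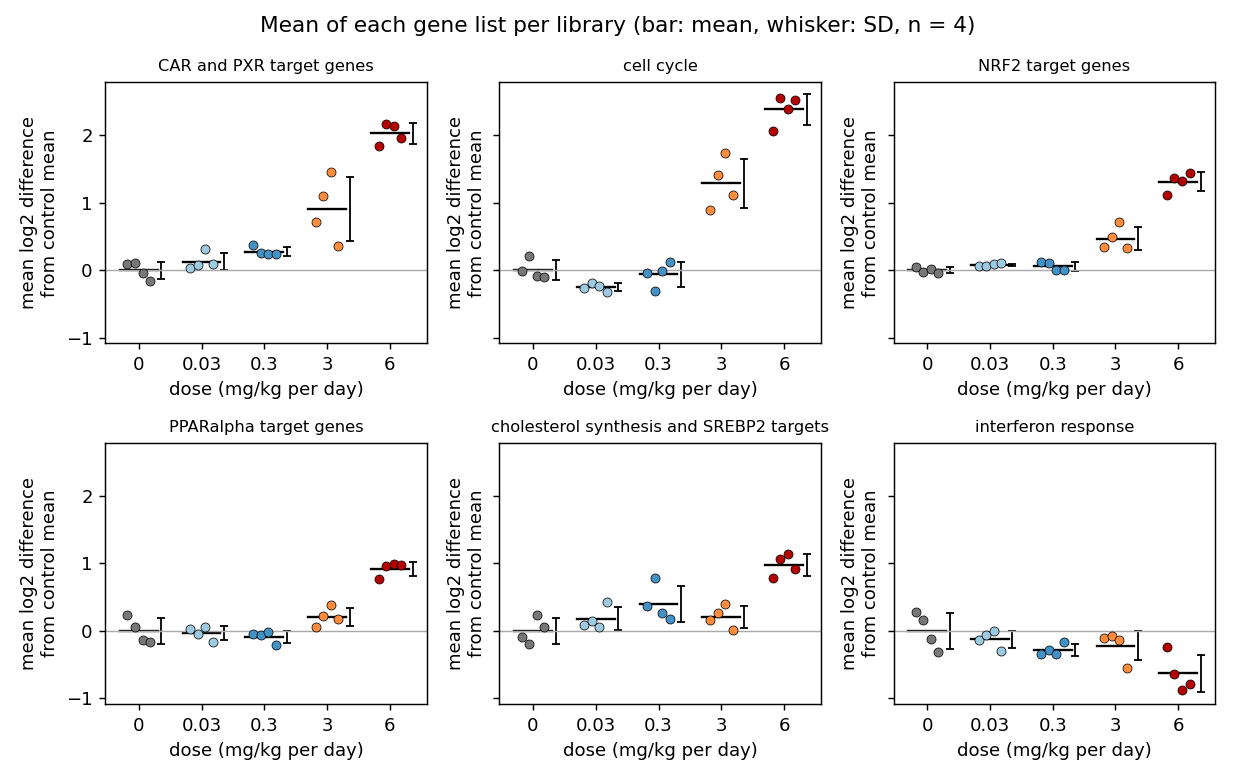
Mean log2 difference from the control mean over the members of 6 gene lists, 1 point per library, by daily dose in mg/kg, with a bar at the mean and a whisker for the SD (n = 4). The CAR and PXR, cell cycle and NRF2 lists lie above all controls in every library at 3 and 6 mg/kg, while the interferon list at 6 mg/kg overlaps the controls.

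The call count at 6 mg/kg was 508 with plate row as a covariate, 254 higher and 254 lower. Over the 2867 probes the median SE then went from 0.25 to 0.48, while their median absolute log2 change went from 1.03 to 1.15 and 2853 had the same sign. With plate column as a covariate, added after seeing the data, the count was 788. The controls held columns 2 to 5 and the 6 mg/kg libraries columns 7 to 10, so column goes with dose. The lower count alone therefore does not show an effect of column. Scaling by total counts alone moved the median log2 change of all probes from 0.01 to 0.15 at 6 mg/kg and from 0.00 to 0.16 at 0.3 mg/kg, and the calls at 6 mg/kg to 1894 higher and 811 lower.

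The comparison of 6 with 3 mg/kg asks which genes went on changing between these doses. Cyp4a14 was higher at 6 mg/kg by a log2 of 4.53 (SE 0.44, edgeR adjusted p = 2.2e-05), Tgm2, a transglutaminase, by 3.02 (SE 0.56), Gsta1 by 2.72 (SE 0.60), Gadd45b by 2.42 (SE 0.31) and Gstm2, a glutathione transferase, by 2.27 (SE 0.36). Serpina4-ps1 was lower by 2.63 (SE 0.60), Dbp, a clock-controlled transcription factor, by 2.43 (SE 0.68), Socs2 by 2.40 (SE 0.49), Gm10681 by 2.39 (SE 0.33) and C8a, a complement component, by 1.87 (SE 0.51). In all, 950 probes passed, 559 higher and 391 lower, and scaling by total counts alone gave 670 higher and 199 lower. This count depends on single libraries: it was 3105 without dose_3 replicate 4, 302 and 408 without dose_3 replicate 1 and 2, and 503, 609 and 601 without dose_6 replicate 2, 3 and 4. On the 8 libraries of these groups alone it was 11. With plate column as a covariate, added after seeing the data, it was 75, 57 higher and 18 lower. The 3 mg/kg libraries held columns 3 to 6 and the 6 mg/kg libraries columns 7 to 10, so column goes with dose here too. Without both dose_3 replicate 4 and dose_6 replicate 4 it was 2478, 1279 higher and 1199 lower.

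Over dose rank, among called genes with a mean of at least 20 CPM, the largest slopes per rank were those of Cyp2c66 at a log2 of 2.59 (SE 0.21, edgeR adjusted p = 9.2e-08), Cyp4a14 at 2.00 (SE 0.26), Gadd45b at 1.61 (SE 0.17), Gsta1 at 1.48 (SE 0.16) and Cyp2c55 at 1.44 (SE 0.16). The steepest falls were those of Gjb1 at -0.78 (SE 0.15), Rps27l at -0.74 (SE 0.14), Fam96a at -0.73 (SE 0.12), Oaf at -0.69 (SE 0.19) and Psenen at -0.67 (SE 0.11), of which Rps27l and Psenen have another probe that did not pass at 6 mg/kg, at 0.06 and -0.46. In all, 2541 probes passed, 1592 higher and 949 lower, and scaling by total counts alone gave 1897 higher and 651 lower. With plate row as a covariate the count was 603, 287 higher and 316 lower, of which 301 were among the 2541.

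Of the 211 probes called at 3 mg/kg, 202 were called in the same direction at 6 mg/kg, 154 higher and 48 lower, where independent lists would share 18.2 and 4.7. Both comparisons use the same control libraries. Simulated groups with no change had a mean of 0.025 calls at 3 mg/kg and 0 at 6 mg/kg, so that their 0 shared calls were fixed beforehand and say nothing of the overlap. They gave a covariance of fold changes of 0.0577 against the observed 0.309 (correlation 0.501 against 0.725). With the controls split into pairs, 1 pair for each dose, the mean over 6 splits was 59.3 shared calls of 64.2 at 3 mg/kg, and a covariance of 0.258. Libraries of both doses came from plate row B and all controls from row A. An effect of row would thus be shared by both comparisons, and neither the simulation nor the split controls can tell it from dose.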

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

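The tests of probe agreement, plate row, GC content, depth, exchanged samples and cell type markers in this part were chosen after the related values were seen, whereas the tests on other splits of the libraries were fixed before their result was seen. In 10 of 145 groups of 4 libraries, 1 library lay far from its group, where chance alone gives 7.25; 4 of the 10 were in dose_3 replicate 4.

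Library-level values that stood out were the total of dose_0.03 replicate 2, 9.95 times 1000000 counts against 9.43 to 9.48 in the rest of its group, and the 23418 probes with a count in control replicate 2, against 19110 to 19721. Single genes that stood out were Cyp7a1 at 348 CPM and Fasn at 35.1 CPM in dose_3 replicate 4, Cyp2b10 at 3990 CPM in dose_6 replicate 4, and Ehhadh at 1066 CPM in dose_6 replicate 1.

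In dose_3 replicate 4, the first principal component was 111 against -14.1 to 0.551 in its group, and its mean correlation with its group was 0.870 against 0.942 to 0.945, and in dose_6 replicate 4 the fourth component was -47.8 against 13.8 to 24.0, and the correlation 0.940 against 0.966 to 0.970. A difference between animals at the gene level would move both probes of a gene. The deviations of the 2 libraries correlated between probes of a gene at 0.103 and 0.221, where fold changes at 6 mg/kg, over 4 libraries, correlated at 0.651 across genes. Libraries of the other groups gave 0.228 to 0.667. The other libraries gave 0.122 to 0.194 at 3 mg/kg and 0.140, 0.163 and 0.619 at 6 mg/kg, but against means that include the library that stands apart. Low values are thus not particular to the 2 libraries, and whether animals differed at the gene level is not settled. Their totals, 8.81 and 8.48 times 1000000 counts, lay within the range of the other 18 libraries (6.82 to 10.3). A trend on transcript GC content took up 4.69% and 7.53% of the variance of their deviations. The trend of dose_6 replicate 4 nevertheless spanned a log2 of 1.35, against at most 0.620 in the others. For a swap of dose_3 replicate 4 with a dose_6 library, no partner lay near the dose_3 mean. The lowest, dose_6 replicate 1, lay at 0.623 between the dose_3 mean (0) and the dose_6 mean (1). Exchanging these 2 labels gave 1915 calls for 6 against 3 mg/kg, against 950 with the real labels, so the position alone does not settle a swap. Dose_3 replicate 4 itself lay at 0.874 to 1.04 on that scale of position, as a dose_6 library with a single wrong label would. The scale covers 1 axis only. The second principal component of this library was 76.4, against -24.3 to -4.30 in the rest of its group and -36.3 to -27.8 at 6 mg/kg. At 4.29 CPM of Cyp4a14 and 564 CPM of Ehhadh, however, the library lay with its group and under the lowest dose_6 library (76.6 and 1066). The position and these genes point opposite ways, so a single wrong label is not settled. A fault of probe ligation or amplification in those wells also stays open and was not tested.

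Probes that fell at 3 mg/kg mostly did so without the other probe of their gene. The ratio of the median change of the other probe to that of the called probe was 0.0527 (95% bootstrap interval -0.0468 to 0.111), against 0.936 for rising probes, which argues against a fall of the whole transcript, though a shift between transcript forms was not tested. With the GC trend removed, 92.5% of these probes were still called. The GC content was that of a transcript of the gene, equal for all its probes. Its removal therefore cannot explain probes of a gene that differ, and the GC content of probe targets was not tested. A candidate explanation is plate row. The only 0.3 mg/kg library in row B lay below those in row A by a median log2 of -0.369 over the falling probes, lower than 10000 random probe sets of like expression. Over the 157 probes that rose at 3 mg/kg the same library lay higher by 0.185, above all 10000 random sets, so plate row is a candidate for those rises too. Over the 1634 probes that rose at 6 mg/kg, which include 154 of these, its median deviation was -0.0792, against the direction of the rise. These values rest on 1 library, however, and dose is otherwise confounded with row. At 6 mg/kg the ratio was 0.526 (0.458 to 0.563) for falling probes, against 0.695 (0.626 to 0.748) for rising probes. With the GC trend removed, 89.4% of the falling probes stayed called. Over them the row B library lay higher by 0.129, against the direction of the fall. As it is 1 library, plate row cannot be told apart there from the effect of dose, and whether whole genes changed is not settled.

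The fall of interferon response genes at 6 mg/kg was not matched by the endothelial markers, which lay above the interferon list by a mean log2 of 0.652 (SD 0.148, 4 of 4 libraries). This argues against a lower share of RNA from all cells other than hepatocytes, and leaves open a change in Kupffer cells, whose markers lay above the interferon list by 0.121 (SD 0.0960, 4 of 4 libraries). The row B library at 0.3 mg/kg lay higher by 0.227 over the interferon genes, against the direction of the fall, but as it is 1 library, plate row cannot be told apart from dose. An effect of the compound is untested.

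Chance regrouping of the libraries is an unlikely source of the calls at 3 mg/kg, where 1 of 35 splits, the real one, gave 211 probes and the highest other gave 5. At 6 mg/kg 1 of 35 gave 2867 and the highest other 0. A share of 1 in 35 is the smallest these splits can reach. Plate row divides these libraries exactly as dose does, so the splits cannot tell row from dose. Chance regrouping is also an unlikely source of the slope calls, with 1 of 100 splits at 2541 and the highest other at 681. It cannot be excluded for 6 against 3 mg/kg, where 2 of 35 splits reached 950; the highest other, with 1915, exchanged dose_3 replicate 4 and dose_6 replicate 1, and those that exchanged dose_3 replicate 4 with dose_6 replicate 2 and 3 gave 768 and 714. At 0.03 and 0.3 mg/kg the real count was 0, which all 35 splits reach by construction, so that the splits say nothing of chance there (highest other counts 0 and 1). For the number of gene lists called at the preset correlation, 5, 15, 6 and 2 of 35 splits reached the real 10, 5, 9 and 16 lists at 0.03, 0.3, 3 and 6 mg/kg. The highest others were 15, 10, 12 and 17. Chance therefore cannot be excluded at 0.03 and 0.3 mg/kg. At 3 and 6 mg/kg every other split that reached the real count exchanged 1 treated library with 1 control, and so kept most of the dose contrast. Splits that exchanged 2 gave 0 to 8 lists at 3 and 0 to 5 at 6 mg/kg. The share of splits thus does not decide on chance at these 2 doses.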

How the results depend on the processing

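Fits without both libraries that stand apart, with plate column and with the GC trend removed were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that groups share. Where nothing else is said, the cause was not tested.

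DESeq2 gave 1, 42, 356 and 1453 probes at 0.03, 0.3 and 3 mg/kg and for 6 against 3 mg/kg. Fits on the 8 libraries compared, with fewer samples behind the spread, gave 4 at 0.3, 44 at 3 mg/kg and 11 for 6 against 3. With a mean of at least 10 CPM, which tests fewer probes, 103, 1781 and 1558 were called at 3 mg/kg, at 6 mg/kg and for the slope. Minimum folds by their own construction lowered the counts: 1.5 gave 72, 767 and 63 at 3 mg/kg, 6 mg/kg and 6 against 3, and a fitted fold of 2 gave 1478 at 6 mg/kg and 448 for 6 against 3. Plate row gave 1, 508 and 603 at 3 mg/kg, 6 mg/kg and for the slope, and plate column gave 1, 788 and 75 at 0.3 mg/kg, 6 mg/kg and for 6 against 3. Row and column both go with dose in these comparisons, so a lower count alone does not show an effect of either. Without both libraries that stand apart the counts were 1, 379 and 2478 at 0.03 mg/kg, 3 mg/kg and for 6 against 3, and with the GC trend removed 1 was called at 0.3 mg/kg.

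Leaving out each library in turn gave 0 to 1 probes at 0.3 mg/kg, 124 to 279 at 3 mg/kg and 302 to 3105 for 6 against 3. The lists called fell to 1, 0, 3 and 6 at 0.03, 0.3, 3 and 6 mg/kg with an estimated correlation, to 1 and 1 at 0.03 and 0.3 mg/kg with fry, and rose to 8 at 0.3 mg/kg with all probes. RLE and upper-quartile scaling kept every count within 1.5 times.

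Among the named genes and these alternatives, signs turned in 3 that had not passed. Of the 34 named genes at 3 mg/kg and the 32 at 6 mg/kg, calls were lost in 17 and 14 with plate row, in 4 and 9 with plate column and in 12 and 1 on the 8 libraries compared, and 52 times and 1 time over the fits that leave out a library. With plate row, Ppara at 3 mg/kg was 0.0712 and Cyp3a11 at 3 mg/kg was 0.0327, which was also its value without both libraries that stand apart. Leaving out each library in turn, Fabp1 at 3 mg/kg ran from -0.0860 to 0.222, Ppara at 3 mg/kg from -0.355 to 0.0577 and Cyp3a11 at 3 mg/kg from -0.798 to 0.0350. In the simulation of 6 mg/kg against control, with 200 changed probes, 37.9% of changes of 2-fold and 1.49% of 1.5-fold were recovered. The real comparison called 2867 probes, of which 1478 had a fitted fold of at least 2. The adjusted threshold is less strict where more probes change, so the simulated shares do not tell what was detectable at 6 mg/kg.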

Other observations

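Zonation markers changed in both directions at 6 mg/kg. Of 26 pericentral hepatocyte markers 6 rose and 8 fell, with Cyp2a5, a P450 of the zone around the central vein, at a log2 of 2.72 (SE 0.26) and Glul, the glutamine synthetase of the same zone, at -1.68 (SE 0.25). Of 26 periportal markers 3 rose and 7 fell, with Gls2, a glutaminase, at -1.02 (SE 0.15) by its main probe and at -0.58 (SE 0.23) by its other probe, which did not pass. Neither list was called by camera (adjusted p = 0.56 and 0.078).

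Acute-phase proteins moved apart at 6 mg/kg, with 7 of 34 members higher and 12 lower. Orm2 and Orm3, forms of orosomucoid, rose by 3.03 (SE 0.36) and 4.87 (SE 0.51), while Fga, a fibrinogen chain, was at -0.98 (SE 0.16) and Lrg1 at -1.31 (SE 0.21). Proteasome subunits rose in 14 of 37 members and fell in 1, the immunoproteasome subunit Psmb9 at -1.04 (SE 0.24), with an adjusted p of 0.12 with an estimated correlation. Of 62 oxidative phosphorylation genes, 4 rose and 5 fell.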
